A study of Sus scrofa domesticus with 8 samples.

How the data were processed

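Nuclei from frozen right atrial free wall of 8 male pigs aged 10 weeks, 4 control and 4 PAB, were profiled by droplet-based nuclear RNA sequencing, with 1 library per animal. The labels do not spell out PAB, which in this field usually stands for pulmonary artery banding, a surgical narrowing that loads the right heart. Nuclei were purified by flow cytometry, and libraries were made at the University of Minnesota Genomics Center, per the labels. Each deposited matrix held raw UMI counts per gene and nucleus, made by the authors with Cell Ranger 7.2.0 on genome build Sscrofa10.2, per the submitters' processing notes. The gene annotation release and the handling of intronic reads were not stated. No barcode in the deposited matrices held fewer than 500 UMIs, so barcodes had been filtered before deposit. The labels gave no batch, day of surgery or sequencing run, and the number in each animal's title was not treated as a pair. A label named the cell type of every sample as tissue of another chamber, while the tissue label read right atrium, and the tissue label was followed.

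The matrices held 129701 barcodes and 21607 genes. Of these genes, 8091 had no symbol in the deposited tables, and 1750 of them were given a symbol from a reference table of gene identifiers. A gene with neither keeps its identifier. Nuclei with at least 500 UMIs and at most 5% mitochondrial counts were kept, which left out 45 barcodes. Doublets were scored with Scrublet's method in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes and at most 15%. The automatic thresholds marked 52.4% of control 1, 64.8% of PAB 2 and 0.3% of control 3, so the median of the 8 thresholds, 0.324, was applied to every library. That step left out 14045 barcodes, and 115611 nuclei were kept. Kept nuclei per library numbered 13946, 18145, 5485 and 16373 in control 1 to 4 and 21613, 14858, 13344 and 11847 in PAB 1 to 4.

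Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes gave 30 principal components, which were corrected between libraries by code written after the Harmony algorithm (50 clusters, sigma 0.1, theta 2, lambda 1, 10 rounds). A graph of 15 neighbours was clustered with leidenalg 0.10.2 at resolution 1, which gave 34 clusters. Clusters were named from 16 fixed marker sets. A name needed at least 3 markers raised 2-fold, a score of 0.7, 150 nuclei, and no lead by another class's markers among the 10 leading genes. The 34 clusters gave 13 named classes, and 7 clusters stayed unnamed. Class names describe likeness to marker sets, not sorted cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

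The animal was the replicate throughout. Each class's percent of kept nuclei, and each library's depth and quality, were compared by exact permutation of the group labels, two-sided, over 70 arrangements, where 0.0286 is the smallest p that 4 against 4 can give. The Benjamini-Hochberg method adjusted over the classes. For gene tests, counts were summed per library over all kept nuclei and over each class, for libraries with at least 20 nuclei of the class and classes with at least 3 such libraries in each group. This gave 11 tested classes. edgeR 4.0.16 in R 4.3.3 fitted quasi-likelihood models with TMM scaling and the filterByExpr filter, at an adjusted p of 0.05 within each class. The difference between the PAB effects in cardiomyocyte-like and fibroblast-like nuclei was tested as an interaction, with the animal as a term. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside edgeR. Fold changes are log2 of PAB over control with a standard error (SE), and levels are CPM, counts scaled by library total and TMM factor, with the SD between animals.

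For 36 gene lists in 50 list and class pairs, camera was run at its preset inter-gene correlation of 0.01, adjusted over the 50 pairs, with camera at an estimated correlation and fry beside it. The lists covered fuel use, contraction, ion channels, signalling, stress, matrix, endothelial, immune and cell cycle genes, and each list is given with its result. Genes were named by a rule: in each class, genes with a symbol, an adjusted p under 0.05, groups that did not overlap and a mean of at least 10 CPM, the 10 largest rises and 10 largest falls in cardiomyocyte-like and fibroblast-like nuclei and 5 of each elsewhere, or, where fewer than 5 passed, the 5 with the smallest p. In each list, up to 4 called members or, with none, 2 members by the smallest p were named, and NPPA, NPPB, MYH6 and MYH7 were always named in cardiomyocyte-like nuclei. Genes named beyond the rule are said to be so, and the text leaves out a few genes that the rule names. The tests, lists, markers, naming rule and 37 alternatives were chosen before the data were examined.

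Precision was tested on simulated data: counts were drawn from each class's means, library sizes and dispersions, with 200 genes changed in the PAB libraries. Of genes changed 4-fold, edgeR recovered 84.8% in all nuclei, 68.2% in cardiomyocyte-like, 87.9% in fibroblast-like, 90.9% in myeloid-like and 80.3% in B cell-like sums. Of genes changed 2-fold, it recovered 16.7%, 6.1%, 16.7%, 33.3% and 22.7%, and 65.2% in T and NK cell-like sums. Of genes changed 1.5-fold it recovered 30.9% in T and NK cell-like sums and at most 4.4% in the other classes. Genes called without having been changed numbered 0 to 11 per class. The interaction test recovered 61.5% of 4-fold differences. A count of 0 therefore says little about changes of 2-fold or less outside T and NK cell-like nuclei.

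Alternatives were another scaling (RLE), no filter on low counts, DESeq2, limma-voom, a minimum of 1000 UMIs, at most 1% mitochondrial counts, doublets kept, no correction between libraries, clustering at resolution 2, equal numbers of nuclei per library, a filter on genes under 25% of their level in the class where they are highest, log-ratio shares (0.5 added to counts), a replicate block, and each animal left out in turn. After the data had been seen, 7 more were added, which left out clusters or libraries or placed unnamed clusters in their nearest class. All other splits of the animals into groups of the same size were fitted as well. Chromosome coordinates are not printed, because the annotation that was used is not stated. Gene order for the test of neighbouring genes came from a reference annotation of a newer build. Velocity, trajectories and ligand and receptor inference were not attempted, and lymphatic, mast cell and neutrophil marker sets named no cluster.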

Results

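Right atrial free wall nuclei from 4 control and 4 PAB pigs were profiled, with 1 library per animal, and the labels name the comparison of PAB with control as the design. The libraries held 44459358, 52016536, 13577842 and 43250843 UMIs in control 1 to 4 and 65270491, 59915788, 33418562 and 31707289 in PAB 1 to 4. Kept nuclei had medians of 2292, 1982, 1632 and 1832 UMIs in control and 2016, 2309, 1675 and 1839 in PAB. Fold changes are log2 of PAB over control with the SE, and other ± values are the SD between animals, with n = 4 per group except in B cell-like nuclei (n = 3).

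Cardiomyocyte-like nuclei were the largest class, at 46.8 ± 10.24% of nuclei in control and 39.5 ± 10.0% in PAB. Fibroblast-like nuclei, whose marker genes include collagens, made up 14.5 ± 2.79% and 11.1 ± 4.63%. Myeloid-like nuclei made up 8.34 ± 3.74% and 13.6 ± 4.36%, and T and NK cell-like nuclei 9.03 ± 1.81% and 11.3 ± 4.01%. Mesothelial- and epicardial-like nuclei, from the outer lining of the heart, were 0.302 ± 0.169% in control and 0.103 ± 0.036% in PAB, with every PAB library below every control library (exact permutation p = 0.0286, the smallest that 4 against 4 can give, two-sided, adjusted p = 0.371). That exact permutation p was 0.0571 at clustering resolution 2 and 0.0857 without correction between libraries. It was 0.0857 without PAB 1, 0.114 without PAB 2, PAB 3 or PAB 4, and 0.0286 without each control in turn. The difference of the means was −0.127 points without control 4, against −0.199 with it. Proliferating nuclei, marked by MKI67 and TOP2A, were 1.46 ± 0.607% and 2.91 ± 1.51% (exact permutation p = 0.0571, adjusted p = 0.371), with 5.05% in PAB 1. Their difference was 0.735 points without PAB 1 (exact permutation p = 0.143), against 1.45 with it. Vascular endothelial-like nuclei were 4.88 ± 0.732% and 5.86 ± 2.00%, endocardial-like 2.56 ± 1.78% and 2.25 ± 0.432%, pericyte-like 4.78 ± 1.30% and 5.30 ± 1.93%, and smooth muscle-like 0.538 ± 0.214% and 0.631 ± 0.247%. Schwann- and neuron-like nuclei were 2.08 ± 0.704% and 2.40 ± 0.631%, B cell-like 0.181 ± 0.0601% and 0.293 ± 0.205%, and adipocyte-like 0.672 ± 0.303% and 2.04 ± 2.20%, with 5.25% in PAB 3. The adipocyte-like cluster of 1469 nuclei scored 1.59 for adipocytes and 1.53 for fibroblasts. At resolution 2 a cluster of 328 nuclei had the adipocyte name, and the difference of the means was 0.415 instead of 1.37 points. No class passed the Benjamini-Hochberg adjustment, and exact permutation p for classes other than mesothelial and proliferating ranged from 0.143 for myeloid-like to 0.743 for pericyte-like nuclei. Without PAB 3 the difference was −5.66 points for fibroblast-like nuclei (exact permutation p = 0.0286, adjusted p = 0.297), against −3.42 with it, and 0.301 for adipocyte-like nuclei. Without PAB 1 the adipocyte difference was 1.95 points (exact permutation p = 0.0286, adjusted p = 0.371).

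**Figure D1:**
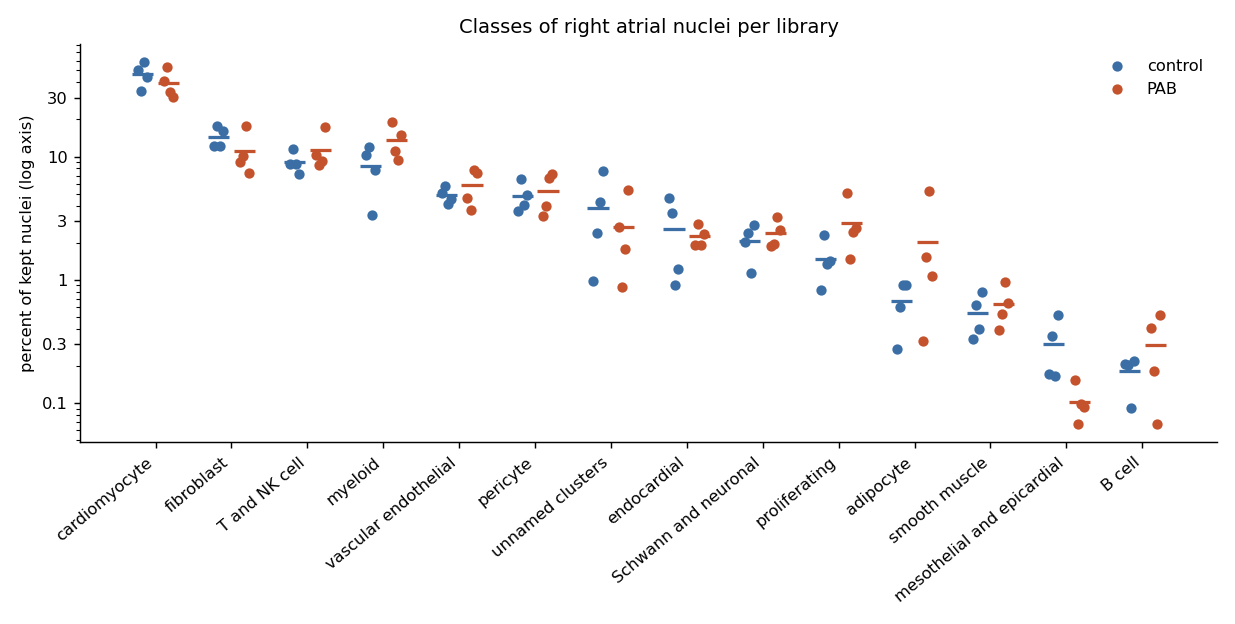
Percent of kept nuclei in each class, named by likeness to marker sets, with 1 point per library and control and PAB side by side. Mesothelial- and epicardial-like nuclei are the class whose groups do not overlap.

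After correction between libraries, cardiomyocyte-like nuclei fell into clusters that differed by animal more than by group. The cluster led by GRIA1, COLQ and FAM184B held 72.5% of the cardiomyocyte-like nuclei of PAB 1 and 48.1% of those of PAB 3, against 8.79% in PAB 4 and 4.68% in control 3. The cluster led by NPPB, ACTC1, BMP10 and MYH7, genes of contraction and natriuretic signalling, held 62.9% of those of control 1 and 57.6% of those of PAB 2. A cluster with ESR2, TBX3 and CACNA1D among its leading genes held 53.0% in control 3, 19.9% in PAB 3 and at most 4.16% elsewhere. It scored 0.89 for cardiomyocytes and 0.80 for smooth muscle. At clustering resolution 2 the cluster led by ESR2 held 175 nuclei of PAB 3 instead of 887. A cluster named fibroblast at that resolution held 706 nuclei of PAB 3, while the ESR2 cluster kept 1631 of control 3. Without correction between libraries the cluster led by ESR2 held 35 nuclei of control 3 and 114 of PAB 3. A cluster led by GGT5 and CUBN, which scored 1.05 for cardiomyocytes and 0.96 for fibroblasts, then held 1858 and 739. The control 3 and PAB 3 parts of the ESR2 cluster are therefore both uncertain. With the correction, clusters led by FAAH, by TINAG and FRZB, and by CACNA1E and SYT14 came to 86.6% from control 2, 92.1% from control 4 and 100% from control 3, and a cluster with AGT and SYNM came to 96.2% from PAB 4. The cluster with SERPINB2, DUSP5 and FLNC held 28.8% in control 4 and 27.4% in PAB 4. For these clusters the exact permutation p, two-sided, ranged from 0.2 for the GRIA1 cluster to 1.0 for the CACNA1E cluster. Without the correction, no cluster had FAAH, TINAG, CACNA1E or AGT among its 10 leading genes, so these clusters depend on that step. The largest cardiomyocyte-like cluster then held 580 to 3759 nuclei of every library. A cluster with NPPB and ACTC1 among its leading genes still held 5742 nuclei of control 1 and 3903 of PAB 2, out of 10699. With the correction, a cluster that could not be named, led by TNC, CCL2 and PTX3, held 6.44% of all nuclei in control 4 and 3.19% in PAB 4.

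**Figure D2:**
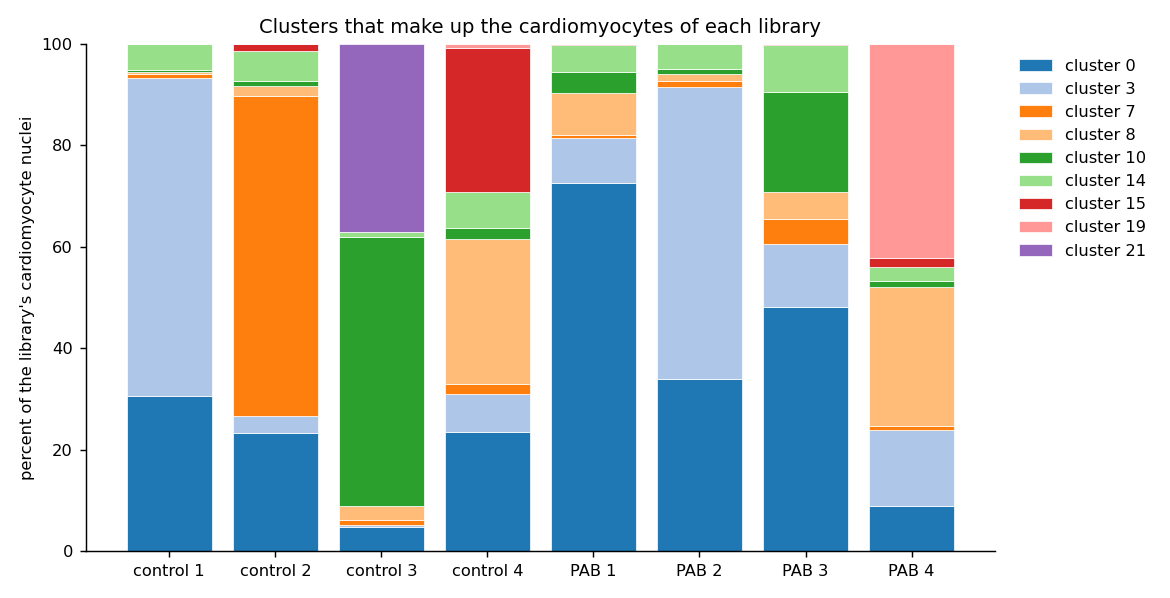
Share of each library's cardiomyocyte-like nuclei in each cardiomyocyte-like cluster found after correction between libraries, in percent, for 4 control and 4 PAB libraries. Most libraries are dominated by a cluster that is small in most others.

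Nuclei had a median of 1141 ± 102 genes in control and 1142 ± 102 in PAB, 1934 ± 278 and 1960 ± 271 UMIs, and 0.0527 ± 0.00695% and 0.0511 ± 0.00337% mitochondrial counts. Control 3 had the fewest nuclei (5485) and PAB 1 the most (21613). PAB 2 had 21.8% of its barcodes marked as doublets, and control 3 had 1.1%. Exact permutation p for nuclei, UMIs, genes and mitochondrial percent ranged from 0.629 to 1.0, two-sided.

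Summed over all nuclei, 1 gene passed edgeR: ENSSSCG00000027848, which has no symbol. It rose from 13 ± 2.36 to 66.1 ± 13.6 CPM (log2 fold change 2.34, SE 0.20, adjusted p = 0.0101) and is named outside the rule because it was the whole count. This gene, like FAM184B, was among the leading genes of the GRIA1 cluster. That cluster averaged 20.5 ± 11.06% of cardiomyocyte-like nuclei in control and 40.85 ± 26.65% in PAB (exact permutation p = 0.2). Whether a shift between clusters gave the call was not tested over all nuclei. The call ended when control 2, control 3 or PAB 3 was left out, with adjusted p of 0.0972, 0.111 and 0.0550 at log2 fold changes of 2.36, 2.35 and 2.29, in a range over all alternatives from 1.1e-22 to 0.486. Of 15843 genes tested, 1014 had an unadjusted p under 0.05, and DESeq2 called 55 and limma-voom 1. The 5 named genes with the smallest p did not pass: the scavenger receptor gene STAB1 (1.22, SE 0.22), FAM184B (1.45, SE 0.28), the glutamine transporter gene SLC1A5 (0.92, SE 0.18), EFR3B (1.42, SE 0.28) and the respiratory complex gene UQCRFS1 (−0.86, SE 0.18), each with an adjusted p of 0.624. STAB1 averaged 42.8 ± 13.4 CPM in control and 99.9 ± 13.5 in PAB, and UQCRFS1 65.5 ± 14.4 and 36.1 ± 4.22. The groups did not overlap in 343 genes higher and 290 lower in PAB, 4.0% of the genes tested, where 2.9% would be separated by chance.

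Cell cycle genes were higher in PAB over all nuclei, in 19 of 20 measured members (median log2 fold change 0.48, camera adjusted p = 9.9e-08). With an estimated correlation between genes the p was 0.0613, and by fry it was 0.0553. In 35 splits of the animals, camera at the preset passed a median of 13 list and class pairs, against 4 in the real split. A list that passes camera at the preset, here and below, is therefore no rare outcome among splits. Of the members, 3 passed when adjusted over the list alone and 0 over all genes: MKI67 (0.88, SE 0.24, 6.13 ± 1.76 and 11.4 ± 2.48 CPM), CENPF (1.10, SE 0.32, 13.1 ± 4.15 and 28.1 ± 11.3 CPM) and ASPM (0.94, SE 0.28, named outside the rule). Without the proliferating nuclei the median was 0.18 and the adjusted p 0.445, in a range over alternatives from 9.7e-12 to 0.748. Each proliferating cluster was given as parent the class with the next best marker score, only 0.81 for the cardiomyocyte-like one of 1724 nuclei. At resolution 2 the like cluster held 1046 nuclei. A cluster of 136 nuclei, too few to name, then scored best for proliferating and next for fibroblasts. The cardiomyocyte-like share may therefore mix parent classes. Among parent classes, the cycling share averaged 1.92 ± 0.975% and 4.15 ± 3.39% in cardiomyocyte-like nuclei, with 8.75% in PAB 1. It averaged 3.54 ± 2.45% and 5.31 ± 2.71% in T and NK cell-like nuclei, 2.51 ± 1.62% and 3.89 ± 1.20% in vascular endothelial-like nuclei and 1.65 ± 0.809% and 1.63 ± 0.547% in myeloid-like nuclei. In cardiomyocyte-like nuclei alone, 11 of 17 cell cycle genes were higher (median 0.14, adjusted p = 0.363). There MCM2 was at 1.43 (SE 0.85), and −0.34 without PAB 1, and CCNE2 at 0.46 (SE 0.29). In fibroblast-like nuclei 4 of 8 were higher (median 0.11, adjusted p = 0.640), with CENPF at 0.70 (SE 0.31) and CCNE2 at 0.36 (SE 0.35).

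Immediate early genes, which respond within minutes to stimuli and tissue handling, were lower in PAB cardiomyocyte-like nuclei in 14 of 16 measured members (median log2 fold change −0.87, camera adjusted p = 1.0e-05). With an estimated correlation the p was 0.113, and by fry it was 0.163. JUN was at 33.5 ± 21.0 CPM in control and 11.3 ± 3.18 in PAB (−1.56, SE 0.40) and the phosphatase gene DUSP1 at 30.7 ± 14.8 and 12.7 ± 5.82 (−1.27, SE 0.39). Of the members, 0 passed over the list alone or over all genes. The median was −0.05, with 8 members higher and 8 lower, without control 4, and −1.50 without PAB 4. Without the GRIA1 cluster it was −0.49 and the adjusted p 0.129, in a range over alternatives from 3.4e-11 to 0.962. Over all nuclei 13 of 17 were lower (median −0.38, camera adjusted p = 0.0245, estimated-correlation p = 0.318), with IER3 at −1.48 (SE 0.50) and NR4A2 at 0.71 (SE 0.21). There 0 members passed over the list alone or over all genes. That call ended without control 1, control 4, PAB 1, PAB 2 or PAB 3, at medians of −0.28, −0.05, −0.24, −0.29 and −0.29 and adjusted p of 0.189, 0.529, 0.171, 0.236 and 0.313. The range over alternatives was 5.8e-06 to 0.962, and the median was −0.80 without PAB 4. In fibroblast-like nuclei 10 of 15 were lower (median −0.30, adjusted p = 0.366), with EGR1 at −1.72 (SE 0.54) and IER3 at −0.74 (SE 0.43).

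Nuclear-encoded respiratory chain and ATP synthase genes were lower in PAB cardiomyocyte-like nuclei in 46 of 51 measured members (median log2 fold change −0.22, camera adjusted p = 1.5e-04). With an estimated correlation the p was 0.348, and by fry it was 0.249. UQCRFS1, a subunit of complex III, was at 85.5 ± 15 CPM in control and 43.8 ± 6.98 in PAB (−0.96, SE 0.18) and passed when adjusted over the list alone (adjusted p = 0.0204) but not over all genes (0.478). NDUFB11, a subunit of complex I, was at −0.55 (SE 0.19). Without control 1 the median was −0.08 and the adjusted p 0.280, and without PAB 2 the median was −0.35, in a range of adjusted p over alternatives from 5.6e-09 to 0.962. The mitochondrially encoded genes were lower in 10 of 13 in cardiomyocyte-like nuclei (median −0.12, adjusted p = 0.366) and in 9 of 13 over all nuclei (median −0.09, adjusted p = 0.363), with ND1 at −0.30 (SE 0.15) and −0.25 (SE 0.13) and CYTB at −0.25 (SE 0.18) and −0.22 (SE 0.17). Over all nuclei that list passed without control 2, at an adjusted p of 0.0399. Genes of the TCA cycle were lower in 16 of 21 (median −0.15, adjusted p = 0.304), with SDHD at −0.40 (SE 0.22) and SDHC at −0.26 (SE 0.17), and passed without control 2 or control 3, at adjusted p of 0.0366 and 0.0346, while the median was 0.00 without control 1.

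**Figure D3:**
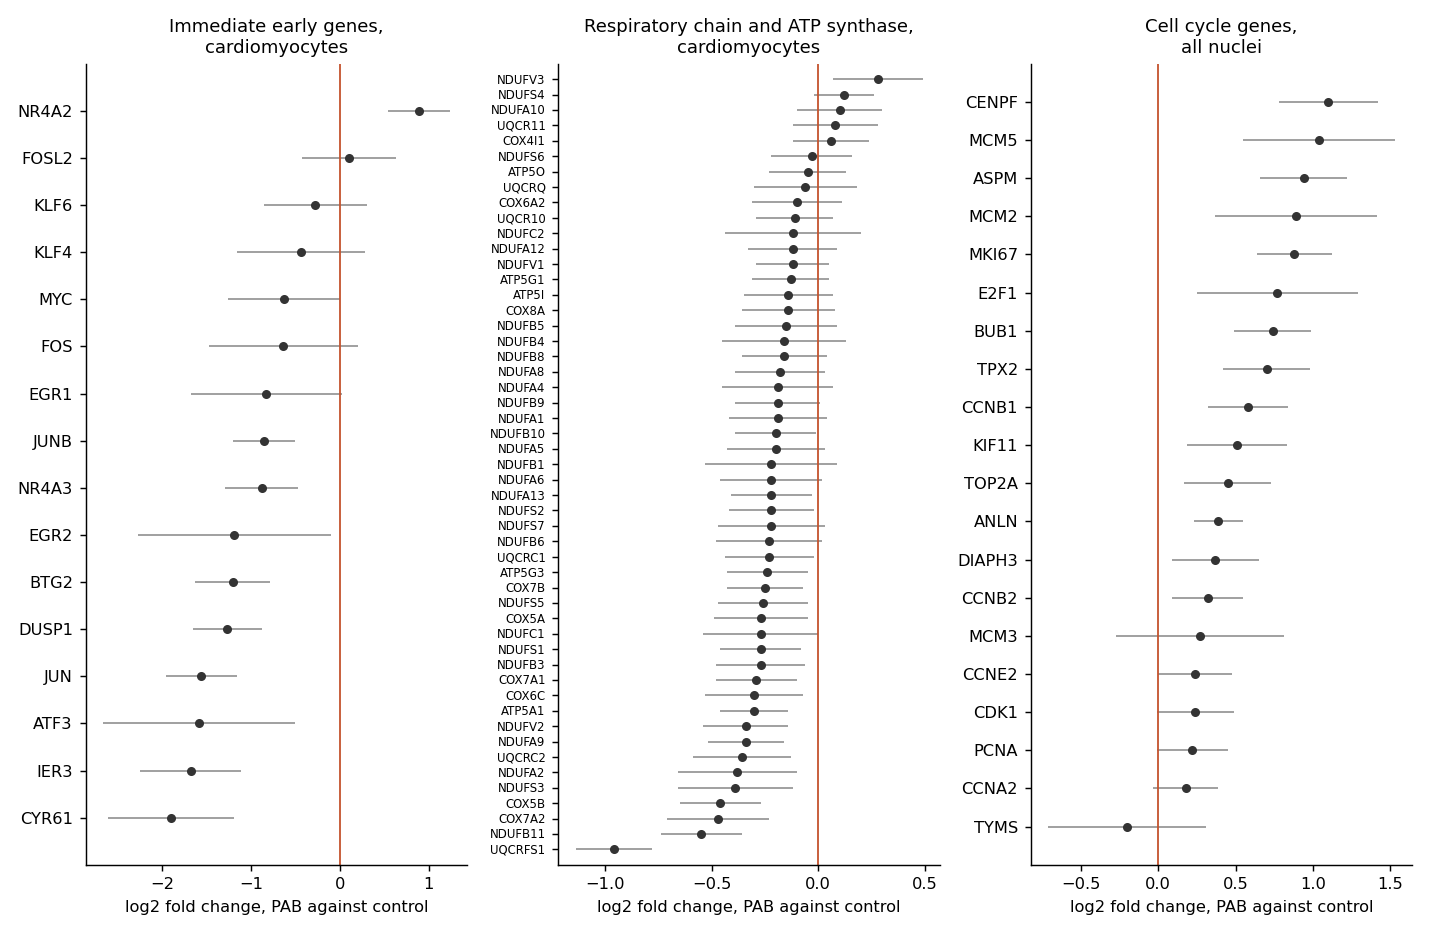
Log2 fold changes of PAB over control for the measured members of gene lists, with 1 point per gene and the SE as a bar. Most respiratory chain and immediate early genes lie below 0 in cardiomyocyte-like nuclei, and most cell cycle genes lie above 0 over all nuclei.

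In cardiomyocyte-like nuclei edgeR called 0 of 14236 genes, with 932 at an unadjusted p under 0.05 and 47 called by DESeq2 and 1 by limma-voom. Among genes that the naming rule admits, those with the smallest p included WFDC1 (25.3 ± 2.96 and 60.9 ± 10.5 CPM, log2 fold change 1.27, SE 0.18, adjusted p = 0.253). The others were EFR3B (49.4 ± 12 and 156 ± 41.4, 1.66, SE 0.25), TINAG (17.9 ± 7.12 and 5.45 ± 0.770, −1.71, SE 0.31), UQCRFS1 and KLHL4 (27.0 ± 5.66 and 67.6 ± 20.5, 1.33, SE 0.25). The natriuretic peptide genes, which atrial muscle releases when stretched, had values of −0.29 (SE 0.38) for NPPA and −0.34 (SE 0.48) for NPPB, and these were 0.04 and 0.06 without control 4. MYH6, the fast atrial myosin, was at 2880 ± 782 and 2814 ± 599 CPM (−0.02, SE 0.26, with the sign turning in several alternatives), and MYH7, the slow myosin, at 168 ± 31.3 and 315 ± 120 (0.91, SE 0.30, adjusted p = 0.687). The groups did not overlap in 234 genes higher and 343 lower, 4.1% of those tested, against 2.9% by chance. ENSSSCG00000027848 had the smallest p of any gene in this class (2.44, adjusted p = 0.0600). Here 1 gene was called without the filter on low counts, with limma-voom, with doublets kept, with the filter for free RNA and without each of the clusters led by GRIA1, NPPB and SERPINB2.

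Other cardiomyocyte lists did not pass camera. The unfolded protein response, which handles misfolded protein, was lower in 14 of 19 members (median −0.16, adjusted p = 0.0534), with the chaperone gene HSPA5 at 13.5 ± 5.14 and 3.46 ± 1.09 CPM (−1.95, SE 0.33, adjusted p over the list 0.00331, over all genes 0.365) and ATF4 at −0.75 (SE 0.21). It passed without control 2, control 3 or PAB 3, at adjusted p of 0.0207, 0.0374 and 0.0120, and for its members in either direction fry gave an adjusted p of 0.00482. Heat shock genes were lower in 11 of 15 (median −0.27, adjusted p = 0.102), with DNAJB1 at −1.33 (SE 0.43) and HSPA1B at −1.17 (SE 0.46). They passed without control 2, control 3 or PAB 4, at adjusted p of 0.00307, 0.0365 and 0.00523, and had 0.943 without control 4. The stretch and hypertrophy response was lower in 21 of 28 (median −0.28, adjusted p = 0.307), with SYNPO2L at −1.02 (SE 0.28), and passed without control 2, control 3 or PAB 4, at adjusted p of 0.0245, 0.0346 and 0.0164, but its median was 0.22 without control 4. Atrial identity factors were higher in 12 of 15 (median 0.18, adjusted p = 0.176), with NR2F1 at 0.57 (SE 0.24) and HAND2 at 0.46 (SE 0.25), and passed without PAB 4 at 0.0458. The interferon response was lower in 13 of 22 (median −0.19, adjusted p = 0.869), with IRF1 at −0.59 (SE 0.34) and HERC5 at −0.56 (SE 0.34), and its median was 0.45 with an adjusted p of 0.00607 without control 3. The cell cycle list in this class passed without control 3 as well, at 0.00607, and its median was −0.03 without PAB 1. The sarcomere list passed without control 3 at 0.0368, and its median was 0.04 without control 4 and −0.02 without control 1.

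Contractile, channel, signalling and fuel genes of cardiomyocyte-like nuclei gave no list past the threshold. Sarcomere genes were lower in 18 of 28 (median −0.12, adjusted p = 0.788), with LDB3 at −0.45 (SE 0.22), and atrial ion channels and gap junctions split 9 and 9 (median 0.00, adjusted p = 0.832). Among channels, the potassium channel subunit gene KCNE1 had 1.61 (SE 0.38) at 1.16 ± 0.506 and 3.51 ± 0.506 CPM and passed over the list alone (adjusted p = 0.0365) but not over all genes (0.681), and the connexin gene GJA1 had −0.53 (SE 0.25). Calcium handling genes were higher in 14 of 25 (median 0.06, mean 0.00, adjusted p = 0.788), with PLN at −0.72 (SE 0.29) and ASPH at 0.63 (SE 0.31). Fatty acid oxidation genes were lower in 14 of 25 (median −0.05, adjusted p = 0.788), with PPARGC1A at −0.45 (SE 0.28) and ACSL1 at −0.38 (SE 0.28). Glycolysis genes were lower in 13 of 23 with the test and median (−0.06) down and the mean (0.01) up (adjusted p = 0.788), with PGAM1 at −0.51 (SE 0.23) and PDHB at −0.34 (SE 0.16). Branched-chain amino acid and ketone genes had a median of −0.01 but a mean of 0.06 and a test up (adjusted p = 0.774), with BCKDHB at 0.58 (SE 0.37) and HIBCH at 0.42 (SE 0.24). The gp130, JAK and STAT list was higher in 12 of 19 (median 0.17, adjusted p = 0.788), with PIM1 and JUNB each at −0.86 (SE 0.33 and 0.35), and its median was −0.48 without PAB 4 and −0.02 without control 1.

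Further lists in cardiomyocyte-like nuclei had medians near 0. Adrenergic and natriuretic receptor genes were higher in 10 of 17 (median 0.07, adjusted p = 0.640), with the phosphodiesterase gene PDE5A at 86.8 ± 13.9 and 142 ± 40.9 CPM (0.72, SE 0.23) and the clearance receptor gene NPR3 at 1.24 (SE 0.52). Ferroptosis and iron genes were higher in 11 of 21 (median 0.00, adjusted p = 0.832), with STEAP3 at 1.13 (SE 0.35) and NCOA4 at −0.35 (SE 0.17). Microtubule and desmin genes split 9 and 9 (median 0.02, mean −0.02, test up, adjusted p = 0.968), with MAPT at 0.91 (SE 0.42) and CRYAB at −0.68 (SE 0.30). Hypoxia genes were higher in 11 of 20 with a median of 0.02 but a mean of −0.08 and a test down (adjusted p = 0.788), with ADM at −1.35 (SE 0.36) and VEGFA at −0.43 (SE 0.18). Ribosomal protein genes were lower in 28 of 43 (median −0.05, adjusted p = 0.445), with RPS16 at −0.73 (SE 0.22) and RPL9 at −0.42 (SE 0.14). Over all nuclei, ribosomal protein genes were higher in 30 of 45 (median 0.10, adjusted p = 0.366), with RPS16 at −0.48 (SE 0.17), and passed without control 3 at 0.0404. Heat shock genes over all nuclei were lower in 8 of 15 (median −0.01, adjusted p = 0.788), with CRYAB at −0.75 (SE 0.28) and HSPB8 at −0.60 (SE 0.27). Red blood cell genes, tested only over all nuclei, were lower in 5 of 6 (median −0.27, adjusted p = 0.102). The carbonic anhydrase gene CA2 was at 3.76 ± 1.73 and 1.17 ± 0.225 CPM (−1.69, SE 0.37, adjusted p over the list alone 0.00661, over all genes 0.671) and HEMGN at −0.33 (SE 0.28). The red blood cell list passed without control 3 or control 4, at 0.0399 and 0.0171.

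In fibroblast-like nuclei edgeR called 0 of 11134 genes, with 539 at an unadjusted p under 0.05 and 11 called by DESeq2 and 0 by limma-voom. The smallest p belonged to the ephrin ligand gene EFNB2, at 18.1 ± 4.07 and 52.7 ± 12 CPM (1.54, SE 0.22, adjusted p = 0.367). PTPRE was at 15.6 ± 5.54 and 55.1 ± 16.7 CPM (1.87, SE 0.31), CERS1 at 1.39 (SE 0.24), RAMP1 at 1.37 (SE 0.27) and LRRC16A at 0.94 (SE 0.20). Fibrillar collagen and matrix genes were higher in 15 of 31, with a median of −0.06, a mean of 0.07 and a test up (adjusted p = 0.190). The symbol SPARC is not unique among the gene entries, and here and below it means ENSSSCG00000017083. This SPARC entry was at 4.49 ± 2.11 and 12.8 ± 5.40 CPM (1.46, SE 0.39) and COL4A2 at 879 ± 212 and 1416 ± 187 (0.70, SE 0.20). Fibroblast activation genes were higher in 13 of 25 (median 0.11, adjusted p = 0.155), with AEBP1 at 0.98 (SE 0.36) and NOX4 at 0.99 (SE 0.51). Matrix proteases and inhibitors were higher in 12 of 19 (median 0.17, adjusted p = 0.190), with ADAMTS15 at 0.82 (SE 0.36) and MMP16 at −0.53 (SE 0.24). Without control 4 these 3 lists passed, at medians of 0.37, 0.30 and 0.53 and adjusted p of 2.8e-05, 1.5e-04 and 0.00840, and without control 2 the matrix and activation lists did, each at 0.0407. Without control 3 the activation list had an adjusted p of 0.847. Cytokine and complement genes split 5 and 6 (median 0.00, mean −0.12, adjusted p = 0.788), with CFD at −0.92 (SE 0.38) and PTX3 at 1.14 (SE 0.48). Hypoxia genes were higher in 13 of 20 (median 0.22, adjusted p = 0.251), with PFKFB3 at 0.97 (SE 0.35) and P4HA2 at −0.56 (SE 0.25), and heat shock genes in 8 of 13 (median 0.11, adjusted p = 0.517), with HSF1 at 0.37 (SE 0.19) and HSP90AB1 at 0.55 (SE 0.39). Unfolded protein genes were higher in 11 of 18 (median 0.02, mean −0.01, test down, adjusted p = 0.832), with HSP90B1 at −0.38 (SE 0.15) and HSPA5 at −0.67 (SE 0.38). Immediate early genes in this class passed without control 2, control 3 or PAB 4, at 0.0366, 0.0189 and 0.0258, but their median was 0.29 without control 1. The groups did not overlap in 3.1% of genes, against 2.9% by chance.

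Endocardial-like nuclei are named after the lining of the chamber. Their cluster scored 1.82 for endocardial and 1.73 for vascular endothelial markers, with 4 of 7 endocardial markers raised, so the name is uncertain. In this class edgeR called 0 of 7472 genes, with 735 at an unadjusted p under 0.05, the highest share (9.8%) among classes of 4 against 4, and 19 called by DESeq2 and 0 by limma-voom. The immune receptor gene CD96 was at 110 ± 31.1 and 27.3 ± 11.6 CPM (−1.96, SE 0.34, adjusted p = 0.272) and FNDC1 at 322 ± 160 and 79.0 ± 25 (−1.99, SE 0.39). The glycosylation genes B4GALT5 and ST3GAL1 were at 1.07 (SE 0.20) and 0.90 (SE 0.17) and the exchange factor gene VAV2 at 0.99 (SE 0.20). Endothelial to mesenchymal and matrix genes were higher in 11 of 14 (median 0.31, adjusted p = 0.0813), with BMP6, a growth factor gene that also served as a marker of the class, at 2882 ± 840 and 6615 ± 2201 CPM (1.20, SE 0.27, adjusted p over the list alone 0.00998, over all genes 0.407) and TGFB2 at 0.71 (SE 0.26). The list passed without control 2, control 3, control 4, PAB 2 or PAB 4, at adjusted p of 0.0402, 0.0346, 0.0371, 0.0485 and 0.0308. Without control 1, edgeR called 3 genes in this class. In this class 5.4% of genes had groups that did not overlap, against 2.9% by chance.

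In vascular endothelial-like nuclei edgeR called 0 of 8875 genes, with 432 at an unadjusted p under 0.05 and 1 called by DESeq2 and 0 by limma-voom. Without PAB 4, edgeR called 1 gene. GSE1 was at 180 ± 10.0 and 289 ± 24.3 CPM (0.67, SE 0.13, adjusted p = 0.867), ITPKC at 0.85 (SE 0.18), ATG2A at 1.24 (SE 0.28) and FRMD3 at −0.89 (SE 0.20). Angiogenesis genes were higher in 13 of 19 (median 0.11, adjusted p = 0.325), with PGF at 0.57 (SE 0.25) and HEY1 at 0.39 (SE 0.20), and the interferon response in 19 of 24 (median 0.11, adjusted p = 0.431), with IFIT5 at 0.66 (SE 0.31) and IRF1 at −0.59 (SE 0.29). Endothelial activation and shear genes were lower in 8 of 15 (median −0.12, adjusted p = 0.788), with the endothelin receptor gene EDNRB at −0.76 (SE 0.26) and VWF at 0.48 (SE 0.25), and their median was 0.28 without control 4. Antigen presentation genes were lower in 10 of 17 (median −0.10, adjusted p = 0.321), with SLA-DRB1 at −0.97 (SE 0.31) and SLA-DQB1 at −0.34 (SE 0.21). Endothelial to mesenchymal and matrix genes were higher in 10 of 16 (median 0.06, adjusted p = 0.448), with BMP6 at 0.41 (SE 0.19) and SPARC at 0.48 (SE 0.38). Endothelial genes whose groups did not overlap made up 3.4%, against 2.9% by chance.

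Pericyte-like and smooth muscle-like nuclei held 0 edgeR calls. In pericyte-like nuclei 243 of 8255 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The growth factor gene PTN was at 38.0 ± 24.2 and 8.63 ± 2.33 CPM (−2.05, SE 0.49, adjusted p = 1.0), PAPLN at −0.85 (SE 0.21), CDH13 at 1.10 (SE 0.28), TSC2 at 0.90 (SE 0.24) and KMT2D at 0.79 (SE 0.21). Pericyte contractile and matrix genes were lower in 12 of 22 (median −0.08, adjusted p = 0.788), with FN1 at 0.57 (SE 0.24) and COL3A1 at −0.54 (SE 0.27). In smooth muscle-like nuclei, of which libraries held 22 to 131, 111 of 3113 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. MYH6 and ANKRD1, which are abundant in cardiomyocytes, were at −1.30 (SE 0.29) and −2.0 (SE 0.50) and turned to 0.56 and 0.10 with doublets kept. TESC was at 1.44 (SE 0.40), NEK4 at 1.02 (SE 0.29) and PEF1 at −1.19 (SE 0.34). Contractile genes split 6 and 6 (median 0.02, mean −0.05, test down, adjusted p = 0.803), with CNN1 at −0.67 (SE 0.45) and TPM2 at −0.40 (SE 0.29). Groups did not overlap in 2.1% of pericyte and 2.8% of smooth muscle genes, against 2.9% by chance.

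In myeloid-like nuclei edgeR called 0 of 10250 genes, with 681 at an unadjusted p under 0.05 and 13 called by DESeq2 and 0 by limma-voom. The tetraspanin gene TSPAN7 was at 23.8 ± 3.36 and 7.36 ± 1.17 CPM (−1.71, SE 0.22, adjusted p = 0.101), CCDC170 at −0.88 (SE 0.15), the folate enzyme gene MTHFD1 at −0.85 (SE 0.15), MAP4K1 at 0.83 (SE 0.16) and VWA5A at 0.92 (SE 0.18). Resident macrophage genes split 5 and 6, with a median of −0.02, a mean of 0.20 and a test up (adjusted p = 0.537), with STAB1 at 611 ± 119 and 1190 ± 509 CPM (0.96, SE 0.28) and F13A1 at 433 ± 297 and 1150 ± 573 (1.42, SE 0.52). Recruited and inflammatory genes were lower in 7 of 10 (median −0.48, adjusted p = 0.646), with VCAN at 0.83 (SE 0.24) and TNF at −1.24 (SE 0.50). Antigen presentation genes were lower in 13 of 19 (median −0.19, adjusted p = 0.307), with CIITA at −0.34 (SE 0.19) and SLA-1 at −0.86 (SE 0.50), and the interferon response in 15 of 25 (median −0.07, adjusted p = 0.363), with IRF1 at −0.68 (SE 0.33) and IFIT5 at 0.57 (SE 0.30). These 3 lists passed without control 1, at adjusted p of 0.0227, 0.00989 and 0.0292. The median of the recruited and inflammatory list was 0.38 without control 4. Myeloid genes whose groups did not overlap made up 3.7%, against 2.9% by chance.

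In T and NK cell-like nuclei edgeR called 0 of 8733 genes, with 642 at an unadjusted p under 0.05 and 3 called by DESeq2 and 0 by limma-voom. The chemokine receptor gene CXCR4 was at 18.9 ± 7.50 and 50.3 ± 13.7 CPM (1.43, SE 0.28, adjusted p = 0.457), DUSP1 at 7.47 ± 0.958 and 17.7 ± 2.75 (1.21, SE 0.24), RABL6 at 0.75 (SE 0.14), PRPSAP2 at 0.64 (SE 0.12) and CHN2 at −0.89 (SE 0.18). Activation and cytotoxicity genes were higher in 9 of 17 (median 0.05, adjusted p = 0.832), with the granzyme gene GZMA at 49.99 ± 8.25 and 80.5 ± 13 CPM (0.67, SE 0.16, adjusted p over the list alone 0.0243, over all genes 0.628) and the cytokine gene IFNG at −0.74 (SE 0.30). Without control 1, edgeR called 2 genes, and with equal numbers of nuclei per library it called 1. In T and NK cell-like nuclei 4.4% of genes had groups that did not overlap, against 2.9% by chance.

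In B cell-like nuclei, tested in 3 against 3 libraries of 27 to 88 nuclei, edgeR called 9 of 1261 genes, which all rose in PAB. PITPNM2 rose from 21.0 ± 2.79 to 488 ± 62.8 CPM (log2 fold change 4.31, SE 0.51, adjusted p = 5.5e-04) and FAM46C, a gene of antibody-secreting cells, from 19.1 ± 18.3 to 461 ± 83.6 (4.24, SE 0.58). The smallest and the largest B cell-like sums held fewer UMIs than those of any other tested class. Control levels of 21.0 and 19.1 CPM therefore rest on very few UMIs per library. The sizes of these rises are imprecise, and the small control SD of PITPNM2 does not show a well measured level. CADPS2 rose by 3.44 (SE 0.49), BTBD11 by 3.17 (SE 0.45) and GAB4 by 2.73 (SE 0.33). The other 4 genes, named outside the rule because they complete the count, were ENTPD1 (2.72, SE 0.52), PTPRE (1.92, SE 0.31), SEC24A (1.63, SE 0.34) and the topoisomerase gene TOP1 (1.52, SE 0.27). DESeq2 called 19 and limma-voom 0, with 122 genes at an unadjusted p under 0.05 by edgeR. Leaving out an animal gave 33 calls without control 1, 20 without control 2 and 5 without PAB 1. The calls without control 1 were 14 higher and 19 lower, and without the filter on low counts 33 higher and 34 lower. Groups did not overlap in 15% of genes, against 10% by chance, and with a minimum of 1000 UMIs the class was too small to test.

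Schwann- and neuron-like and adipocyte-like nuclei held 0 edgeR calls, and DESeq2 and limma-voom called 0 in each. In Schwann- and neuron-like nuclei 251 of 7363 genes had an unadjusted p under 0.05, and CPED1 was at −1.0 (SE 0.24, adjusted p = 1), SPATA7 at −0.65 (SE 0.16), PDZRN3 at 0.93 (SE 0.24), the ubiquitin ligase gene LNX1 at 19.6 ± 2.63 and 6.40 ± 3.30 CPM (−1.62, SE 0.42) and POLA1 at −1.03 (SE 0.27). In adipocyte-like nuclei 254 of 4520 genes had an unadjusted p under 0.05. There STOM was at 109 ± 38.7 and 43.4 ± 2.03 CPM (−1.45, SE 0.29, adjusted p = 0.849), COL6A5 at −1.97 (SE 0.45), TBC1D5 at −0.86 (SE 0.20), the mitophagy gene BNIP3 at 1.60 (SE 0.37) and the brown fat factor gene EBF2 at −2.0 (SE 0.48). At resolution 2 a cluster of 1433 nuclei led by COL6A5 was named fibroblast. Groups did not overlap in 2.4% of Schwann and neuronal genes and 3.6% of adipocyte genes, against 2.9% by chance.

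The PAB effect was not shown to differ between cardiomyocyte-like and fibroblast-like nuclei for any of 13607 genes (edgeR interaction, 0 called, 644 at an unadjusted p under 0.05, smallest adjusted p 0.671). The smallest p belonged to RAMP1, a receptor subunit gene, at −0.13 in cardiomyocyte-like and 1.37 in fibroblast-like nuclei (difference −1.52, SE 0.24). The integrin gene ITGA1 was at −0.73 and 0.98 (−1.70, SE 0.28), RGS2, a regulator of receptor signalling, at −0.96 and 1.19 (−2.07, SE 0.36), PTPN4 at 1.00 and −0.05 (1.07, SE 0.19) and PLEKHA4 at 0.74 and −0.60 (1.48, SE 0.26). Among genes named above, JUN differed by −1.48 (SE 0.30), DUSP1 by −1.73 (SE 0.37) and HSPA5 by −1.22 (SE 0.27), each with an adjusted p of 0.893. DESeq2 and limma-voom were not run on the interaction.

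**Figure D4:**
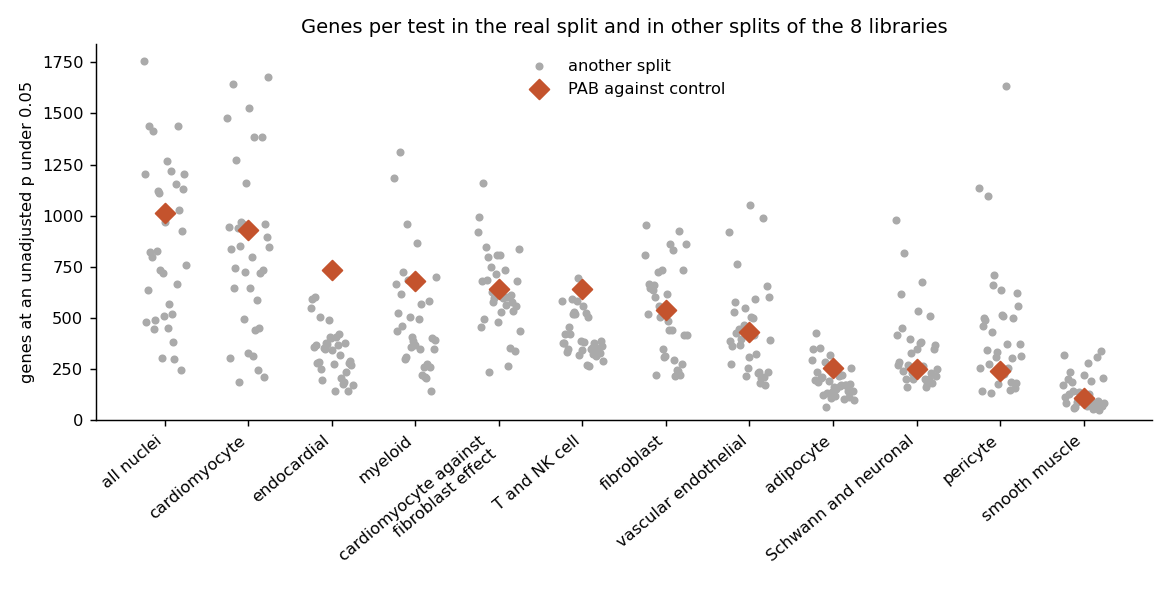
Genes at an unadjusted edgeR p under 0.05 in every split of the libraries into groups of the same sizes, with the control against PAB split marked. These are not genes called after adjustment. Each fit drawn has 35 splits, and the B cell-like class, with 10, is not drawn.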

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

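The share of cycling nuclei per parent class, the count of splits for endocardial-like nuclei and the alternatives without single clusters were tests chosen after the results were seen. Among 356 groups of 4 libraries, 27 held a library far from the other 3, 7.6%, where chance gives about 1 in 20 groups. By library these were 6, 2, 4 and 2 in control 1 to 4 and 5, 2, 3 and 3 in PAB 1 to 4, and they are listed as CPM unless stated.

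In cardiomyocyte-like nuclei, control 1 stood high for HSPA5 (21.2), JUN (64.7) and the branched-chain amino acid enzyme gene BCKDHB (123), control 2 for HAND2 (54.1), control 3 for ND1 (25.6) and control 4 for the chaperone gene CRYAB (335). PAB 1 stood low for TINAG (4.29) and high for HIBCH (25.7) and MCM2 (5.41), and PAB 3 high for KLHL4 (98.2). In fibroblast-like nuclei, control 1 stood high for CCNE2 (39.6), control 4 for IER3 (18.3), PAB 1 for SPARC (20.8) and PAB 4 for HSP90AB1 (82.6), and PAB 4 stood low for MMP16 (121.5). In vascular endothelial-like nuclei, control 1 stood high for EDNRB (189), control 3 low for PGF (9.98), and PAB 3 high for BMP6 (790.2) and low for SPARC (5.98). In myeloid-like nuclei, control 1 stood low for SLA-1 (27.6), with the other controls at 153 CPM or more, and control 3 low for VWA5A (129.5). PAB 2 stood high in smooth muscle-like nuclei for CNN1 (138) and TPM2 (407), PAB 4 high in pericyte-like nuclei for KMT2D (46.5), and PAB 1 low in Schwann- and neuron-like nuclei for LNX1 (1.47). Over all nuclei control 2 stood high for MKI67 (8.76), and B cell-like nuclei made up 0.0912% of control 3.

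Immediate early genes were lower in PAB cardiomyocyte-like nuclei (median −0.87). The camera p of 4.1e-07 was matched or passed in 7 of the 35 splits of the 8 animals, with 1.8e-18 the smallest of the others, so chance is not excluded. Handling before freezing, as a cause that reaches every class, is argued against by 5 other classes, whose middle median was −0.01 (SE 0.0539). The bound set against it was −0.2175, to be cleared by more than the SE, and the bound set for it was −0.435. Fibroblast-like nuclei, not among the 5, had a median of −0.30 (0.29 without control 1), so handling that reached only some classes stays open. A shift between clusters may contribute, since the median was −0.49 without the GRIA1 cluster, and chance, the weight of control 4 and an untested effect of PAB stay open too.

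Respiratory chain genes were lower in PAB cardiomyocyte-like nuclei (median −0.22). A camera p as small as 9.0e-06 came in 8 of 35 splits, with 6.5e-20 the smallest of the others, so chance is not excluded. Free RNA that reaches every class is argued against, for this list only, by a middle median of −0.02 (SE 0.022) in 5 other classes. The bound set against it was −0.055, to be cleared by more than the SE, and the bound set for it was −0.11. Cytoplasmic RNA held on cardiomyocyte-like nuclei alone would not show in those classes, so they cannot decide on it. A shift carried by 1 cluster is argued against by a median of −0.18 without the CACNA1E cluster, the value nearest 0. The clusters left out were those found after correction between libraries. Leaving out 1 cluster at a time cannot decide on a shift spread over several clusters. Mitochondrially encoded genes, another sign of free RNA, had medians of −0.23 in T and NK cell-like and −0.30 in endocardial-like nuclei, so free RNA is not excluded there. What stays open is chance, cytoplasmic RNA held on cardiomyocyte-like nuclei, a shift spread over several clusters, the weight of control 1 and an untested effect of PAB.

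Cell cycle genes were higher in PAB over all nuclei (median 0.48). A camera p as small as 2.0e-09 came in 3 of 35 splits, with 2.3e-15 the smallest of the others, so chance is not excluded. Without PAB 1 the median was 0.34, between the values set for PAB 1 being most of the cause (0.239) and little of it (0.359), so that library alone cannot be told apart from a difference shared by the group. A larger share of the classes that cycle more would leave the cycling share within parent classes no higher, yet it was higher in PAB in 3 of 4, at exact permutation p of 0.229, 0.257 and 0.4, and 0.943 for the class that was not. The cardiomyocyte-like share, 1 of those 3, may mix parent classes. A larger share of the classes that cycle more and an untested effect of PAB therefore stay open.

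Over all nuclei, 11 of 35 splits called as many genes as the real split (1, with up to 2 in the others), so chance is not excluded. A count of 0 is reached by every split, so the 35 of 35 splits are fixed in advance and say nothing in cardiomyocyte-, fibroblast-, vascular endothelial-, endocardial-, pericyte-, smooth muscle-, myeloid-, T and NK cell-, Schwann- and neuron- and adipocyte-like nuclei, where the highest others were 1, 1, 0, 6, 7, 1, 4, 8, 19 and 1. The same held for the interaction, at 0 with up to 2. Several of these splits called many genes, up to 19 in Schwann- and neuron-like nuclei, which points to a structure of the samples other than the study's groups. B cell-like nuclei had only 10 splits, too few for a share under 0.05, with 9 real calls in 1 of 10 splits and 8 in the highest other. Lists past the threshold numbered 4 in the real split and up to 23 in others, and 35 of 35 splits gave as many. The median over the splits was 13, and the 4 of the real split was the lowest count. These counts rest on camera at its preset correlation, while the correlation estimated for the 4 real lists ranged from 0.375 to 0.552. Correlation beyond the preset could give many lists in any split, as could a structure of the samples. No test separated these. Whichever holds, the p of camera at the preset overstates how rare the real split is for these lists. In endocardial-like nuclei, 735 genes at an unadjusted p under 0.05 came in 1 of 35 splits and the highest other gave 602. The class was picked after the results as the one with the highest share of such genes among 11, T and NK cell-like nuclei reached 2 of 35 splits, and no gene passed edgeR. After that choice, chance is not excluded for the count.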

How the results depend on the processing

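Alternatives that left out clusters, proliferating nuclei, or control 3 together with PAB 3 were chosen after the results were seen. Composition changed sign 5 times among 196 alternative values and quality 10 times among 45. Both totals include counts of items past the threshold, which have no sign. None crossed the threshold, which says little about stability, since a lone class at the smallest exact permutation p adjusts to only 0.371. Of 259 alternative counts of genes or lists, 44 moved by more than 1.5 times. Of 854 list values, 49 became stronger, 16 weaker and 2 reversed, with 97 sign changes, and of 3554 values of named genes 49 became stronger, 34 weaker and none reversed, with 13 sign changes. The interaction stayed at 0 calls in each alternative run. The cause was not tested unless stated.

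Genes called over all nuclei numbered 55 by DESeq2, 0 with a replicate block, 0 without control 3 and PAB 3, and 0 to 1 with an animal left out. In cardiomyocyte-like nuclei DESeq2 called 47, and 1 gene was called without the filter on low counts, with limma-voom, with doublets kept, with the free RNA filter and without cluster 0, 3 or 8 (led by GRIA1, NPPB and SERPINB2). DESeq2 called 11 in fibroblast-like, 13 in myeloid-like, 19 in endocardial-like, 1 in vascular endothelial-like, 3 in T and NK cell-like and 19 in B cell-like nuclei. Without the filter the counts were 40 in endocardial-like, 1 in vascular endothelial-like, 9 in smooth muscle-like, 3 in T and NK cell-like, 67 in B cell-like and 56 in adipocyte-like nuclei, and the median of all genes was then 0.123 in B cell-like and 0.132 in adipocyte-like nuclei. Leaving out an animal gave 0 to 1 in vascular endothelial-like (1 without PAB 4), 0 to 3 in endocardial-like (3 without control 1), 0 to 2 in T and NK cell-like (2 without control 1) and 5 to 33 in B cell-like nuclei. Equal numbers of nuclei gave 1 in T and NK cell-like and 3 in B cell-like nuclei, the latter 5 with the free RNA filter and 0 by limma-voom. PTPRE, ENTPD1 and SEC24A lost their call with doublets kept in B cell-like nuclei.

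Lists past the threshold numbered 0 with an estimated correlation, 0 by fry in 1 direction, 9 with a replicate block, 7 without control 3 and PAB 3, and 3 to 15 with an animal left out. The immediate early gene list over all nuclei had adjusted p of 0.937 with an estimated correlation, 0.962 by fry and 5.8e-06 to 0.529 with an animal left out, and in cardiomyocyte-like nuclei 0.807, 0.962, 2.5e-10 to 0.0182, and 0.129 without cluster 0. The respiratory chain list had 0.937, 0.962 and 5.6e-09 to 0.280 (without control 1). The cell cycle list had 0.748, 0.553, 9.7e-12 to 2.9e-04, and 0.445 without proliferating nuclei, whose removal takes out most of the nuclei that carry these genes. The interferon response in cardiomyocyte-like nuclei, not called at a median of −0.19, turned to 0.45 with an adjusted p of 0.00607 without control 3 and to 0.42 with 0.0318 without control 3 and PAB 3, in a range up to 0.817 with an animal left out.

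The replicate block stands for animals of the same number. Correlations between same-numbered animals were 0.081, −0.123, 0.104 and 0.279, and control 1 and control 2 correlated better with another number (0.320 with PAB 2 and 0.124 with PAB 1), so the numbers as a whole do not pair the samples. No label gives a batch, sampling site or litter behind these matches, and no fit blocked on matches picked from the same data. B cell-like nuclei could not be tested with a minimum of 1000 UMIs. A 2-fold change was recovered in simulated data for 6.1% of genes in cardiomyocyte-like, 12.1% in smooth muscle-like and 65.2% in T and NK cell-like nuclei, so recovery did not follow the size of the class.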

Other observations

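The test of neighbouring genes was chosen after the result was seen, and the patterns it and the other tests address were noticed in these data.

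Ribosomal protein genes were higher in PAB myeloid-like nuclei in 42 of 42 members (median log2 fold change 0.34). With an estimated correlation the unadjusted p was 0.0139, and by fry it was 0.00357. At camera's preset correlation, the p of 2.5e-13 was the smallest in 1 of 35 splits, the real one, with 1.3e-12 the smallest of the others. In other classes the splits with a p as small numbered 8 for fibroblast-like, 4 for vascular endothelial-like, 4 for endocardial-like, 6 for pericyte-like and 21 for T and NK cell-like nuclei, at medians of 0.16, 0.18, 0.19, 0.20 and 0.07. The myeloid class was picked because it showed the difference, so chance is not excluded after that choice, and no explanation other than chance was tested.

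Some genes had an unadjusted p under 0.05 in the same direction in at least 3 of 10 classes. There were 175 such genes in the real split, 16 of 35 splits gave as many, and the highest other gave 620, so chance is not excluded and the larger counts point to a structure of the samples. At that p, SRRM2, a splicing factor gene, was higher in 8 of 10 classes (median 0.39) and NAT9 in 7 of 9 (0.63). CENPE was higher in 6 of 7 (1.49), and SLC6A4, the serotonin transporter gene, lower in 6 of 8 (−0.91), again at that p. SLC6A4 in fibroblast-like nuclei was at 627 CPM in PAB 2, among controls at 595 to 715, and at 251, 238 and 131 in the other PAB animals. It was a leading gene of the fibroblast-like cluster, and T and NK cell-like controls had 9.19 to 17.7 CPM. Free RNA from fibroblast-like nuclei is therefore not excluded as a source of its fall in other classes, and was not tested. In fibroblast-like nuclei CENPE was at 46.2 and 57.7 CPM in PAB 1 and PAB 2 but at 8.89 and 8.26 in PAB 3 and PAB 4, with controls at 5.44 to 9.93. FIP1L1 was lower at that p in 6 of 8 classes (−1.21), at 28.8, 29.8, 51.8 and 29.1 CPM over all nuclei in control 1 to 4. It was at 7.12 in PAB 1 and 8.42 in PAB 3 but at 27.2 in PAB 2, close to the controls.

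FIP1L1 and LNX1 follow each other in gene order and KIT lies 4 genes from LNX1. KIT moved the other way, at an unadjusted p under 0.05 in 5 of 8 classes and a median of 0.78 against −0.88 for LNX1, but its class values ran from −0.29 to 1.49. Over all nuclei KIT overlapped between groups, at 62.4 to 115 CPM in control and 93.8 to 209 in PAB. The lower FIP1L1 in most PAB animals and several classes may reflect inherited differences at shared stretches of the genome. If so, such genes would lie near each other more often than random genes. Of the 175 genes, 148 could be placed, and 9 pairs lay within 5 protein-coding genes of each other, against a median of 6 in 10000 random draws, 20.4% of which gave as many. The hypothesis therefore stays open, and without reads or genotypes it cannot be told apart from a shared response.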
